A study of Mus musculus with 3 samples.

How the data were processed

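The series holds 3 single-cell RNA libraries from the livers of 3 wild-type mice, 1 mouse per group. All 3 mice were fed an iron-deficient diet (2 to 6 ppm iron) for 1 week. The mouse of the group IDD was the control, the mouse of IDD+HTF was injected intravenously with 10 mg of holo-transferrin, the iron-loaded form of the plasma iron carrier, and the mouse of IDD+HID was switched to a diet with 2% carbonyl iron for 18 h. The time between the injection and the collection of the liver is not given in the labels. Per the labels' protocols, perfused livers were digested with collagenase and pronase, 5% of the hepatocyte suspension was mixed with 95% of the suspension of the other cells, and 10x Genomics Chromium droplet libraries were made. The share of each cell class therefore reflects the mixing as well as the liver.

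The deposited values are counts of unique molecular identifiers (UMIs) per barcode and gene, whole numbers with no normalization and with every barcode kept. The submitters' processing notes name the genome build GRCm38 and Seurat 4, and the aligner and the counter are not given in the sources used here. Of the 55421 gene identifiers in each library, 55154 had a symbol and 54587 matched GENCODE M21 (GRCm38) with their version, so the annotation behind the counts was close to that release. Symbols and positions were taken from GENCODE M21, and 213 identifiers that share a symbol with another were kept apart. No library held columns of other samples.

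The limits on cells, the classes' markers, the gene lists, the named genes and the tests were chosen before the data were examined. Cells were barcodes with at least 1000 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5 with an expected doublet share of 6%, called 1.72% of the IDD, 0.156% of the IDD+HTF and 0.197% of the IDD+HID barcodes, which were removed. At under 0.5% in the latter pair of libraries the caller has not worked there, and doublets remain among the cells. Counts were scaled to 10000 per cell, 2000 variable genes with a UMI in at least 10 cells were chosen with every gene of the gene lists left out, scaled values were limited to 10, and 30 principal components with 15 neighbours fed Leiden clustering at resolution 1 (igraph 0.11.9, 10 iterations, seed 1). The 24 clusters were named from 20 fixed marker lists by the mean log2 ratio of at least 3 detected markers and by the markers among the top 10 genes. The thresholds of the naming were set after the cluster profiles were seen. They were a pseudocount of 20 CPM, a mean log2 of at least 1 and a lead of at least 0.5 over the next type. Names of the 13 classes end in "-like" because they rest on markers alone, and 4 clusters stayed unnamed.

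Counts were summed over the cells of a class per library and given as CPM, the counts per 1000000 UMIs of the class total. Ratios between libraries are ratios of CPM as log2 or fold, with exact conditional binomial 95% intervals, and CPM carry exact Poisson intervals. Shares of cells carry Clopper-Pearson intervals, which are exact except for the shares after thinning described below. A share of 0 is instead given with the share that 3 counts of the total would make. All of these intervals and limits cover counting error only. With 1 mouse per group there is no replicate check on any difference, no test across mice was possible and no p-value is given. A gene counted as measured with at least 50 UMIs in the pair of libraries together. Where a gene had 0 UMIs in a library, its fold is written as a lower bound from a floor of 3 counts there. Shares of cells with a UMI of a gene were computed as the expectation over all draws that thin each cell to 1000 UMIs, a choice made after a single draw was seen. The expected counts are not whole numbers, so the intervals of these shares are approximate.

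For 22 gene lists the members at least 1.5-fold higher or lower were counted, as a rule of size. The lists were iron handling, BMP ligands and BMP-SMAD targets, BMP receptors, NRF2 targets, lipid peroxidation and ferroptosis, integrated stress and unfolded protein response, immediate early and dissociation genes, hypoxia, NF-kB and cytokines, interferon response, acute phase, heme and erythrocyte recycling, heme synthesis, pericentral and periportal endothelial zonation, endocytic receptors, circadian clock, sterol synthesis, fasting and fat oxidation, cell cycle, angiocrine factors and a sex check. The median log2 ratio of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Bmp6, Bmp2, Hmox1, Nqo1 and Ftl1 were also placed each among single genes within 0.5 log2 of its expression, a step that was not in the plan. Classes needed at least 50 cells in each library compared.

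Named genes followed a rule fixed before the data were examined. It takes 12 genes whatever their values (Bmp6, Bmp2, Tfrc, Fth1, Ftl1, Slc40a1, Slc39a14, Hmox1, Nqo1, Id1, Smad6 and Smad7). It adds the 10 genes higher and the 10 lower in the sinusoidal endothelial-like cells, or 5 and 5 in Kupffer-like and hepatocyte-like cells, ranked by the interval end nearest a ratio of 1. Those genes had to exceed their CPM in droplets with 100 or fewer UMIs in the library where they were higher. Mitochondrial and ribosomal protein genes, genes without a symbol, markers of other classes and the sex check were left out of that ranking. Per list, 2 to 4 members of highest rank are named. Between IDD+HID and IDD+HTF only genes already named or fixed are given. Hamp was fixed in the plan for hepatocyte-like cells, and Hamp2 was added after its values were seen. Some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

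The scripts that compute ratios and intervals were tested on simulated data drawn from the real means and class totals, with 200 genes set at 1.5-, 2- or 4-fold. In simulated sinusoidal endothelial-like cells, 96.0%, 95.9% and 95.8% of the intervals of unchanged genes held the true ratio for IDD+HTF over IDD, IDD+HID over IDD and IDD+HID over IDD+HTF. Counting error alone put 0.912%, 2.37% and 0.27% of those genes past 2-fold, and 100% of genes set at 4-fold passed it in each comparison. A gene set at 1.5-fold in these cells therefore needs its interval beside it.

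In all, 32 alternative settings were tried. Those chosen before the data were examined vary the UMI minimum, the mitochondrial limit, doublet removal, the naming of classes, the clustering resolution, the scaling (TMM from edgeR 4.0.16 in R 4.3.3 and median-of-ratios size factors), the weighting of cells, thinning, a subtraction of free RNA, the genes in the total, the minimum per gene and the fold. Those chosen after the data were seen are clusters 1, 2 or 6 alone, clusters 3 or 9 alone for Hmox1 in Kupffer-like cells, classes without clusters of shallow cells, totals without ribosomal RNA and repeats, removal of the 6% of cells with the highest doublet scores, and a single thinning draw. Free RNA was read from droplets with 100 or fewer UMIs, which were otherwise not analysed here apart from values named below as theirs. Genes that share reads with close copies (Gm10076 with Rpl41, Gm5148 and Hist1h2be) are reported as uncertain. Whether reads were assigned to genes in the same way in the 3 libraries is not given in the sources used here, so genes with 0 UMIs in a library and over 100 in another, such as AC166102.1 and Prss29, are open to it. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.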

Results

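Gene expression was measured in single liver cells of 3 mice that had eaten an iron-deficient diet, 1 kept on it (IDD), 1 given holo-transferrin (IDD+HTF) and 1 switched to a high-iron diet (IDD+HID). The libraries held 34552858, 55478904 and 75404660 UMIs in that order, over 1635467, 1798970 and 2166553 barcodes. Barcodes with at least 1000 UMIs numbered 6921, 8888 and 10900. Of these, 1973, 4162 and 4625 also had 300 genes, and 1334, 3208 and 3545 passed the mitochondrial limit. After doublet removal 1311, 3203 and 3538 cells remained, with medians of 3639, 4449 and 8596 UMIs per cell. Droplets with 100 or fewer UMIs held 10.9%, 3.94% and 3.36% of all UMIs. Ribosomal RNA and repeats made up 24% of the UMIs in such droplets of IDD, 8.36% of IDD+HTF and 6.04% of IDD+HID.

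Sinusoidal endothelial-like cells, which line the liver's capillaries, were the largest class in IDD and IDD+HID. They made up 26.6% of cells in IDD (95% interval 24.2 to 29.1), 25.0% in IDD+HTF (23.5 to 26.6) and 34.0% in IDD+HID (32.5 to 35.6). Kupffer-like cells, the resident macrophages, made up 14.0% (12.2 to 16), 15% (13.8 to 16.3) and 17.6% (16.3 to 18.9). Hepatocyte-like cells came to 18.6% (16.5 to 20.8), 30.9% (29.3 to 32.5) and 7.32% (6.48 to 8.23). Stellate-like cells came to 10.4%, 4.56% and 3.53%, B-like cells to 6.94%, 5.62% and 12.9%, and T-like cells to 6.25%, 4.21% and 7.41%. Vascular endothelial-like cells came to 2.90%, 2.00% and 2.91%, and plasmacytoid dendritic-like cells to 1.75%, 2.25% and 3.48%. NK or ILC1-like, neutrophil-like, cholangiocyte-like, mesothelial-like and smooth muscle or portal fibroblast-like cells each stayed under 2.5% in every library. Unnamed clusters held 9%, 7.90% and 6.11% of cells.

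**Figure D1:**
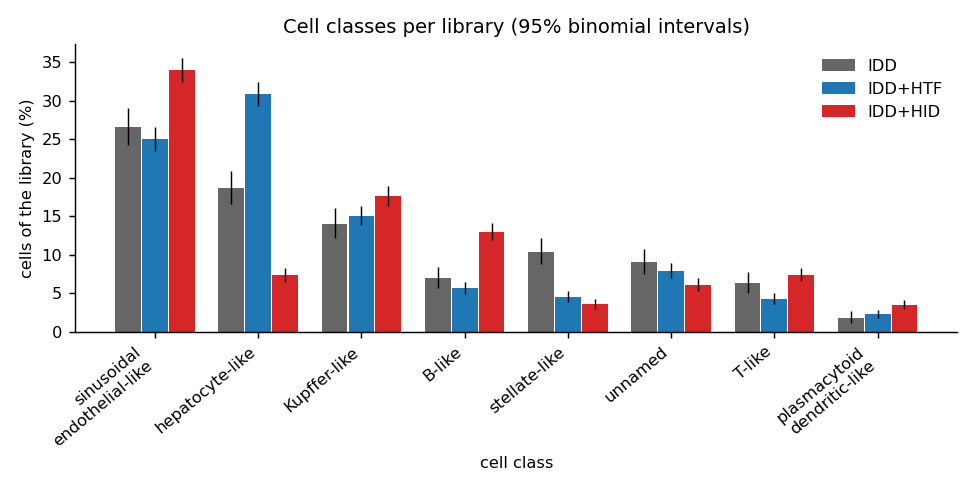
Share of cells in each class per library, with exact 95% binomial intervals. Sinusoidal endothelial-like cells made up 26.6%, 25.0% and 34.0% of cells in IDD, IDD+HTF and IDD+HID.

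The sinusoidal endothelial-like class was made of clusters 1, 2, 14 and 18, and the libraries filled them unequally. Cluster 1, led by Apold1, Cxcl10, Gja1 and Iigp1, held 86, 422 and 596 cells in IDD, IDD+HTF and IDD+HID. Cluster 2, led by Cyp4b1, Gpr182 and Clec4g, held 232, 293 and 442. Cluster 14, of shallow cells, held 28, 64 and 125, and cluster 18, led by Mt2, Asb4, Mt1 and Rasd1, held 3, 23 and 41. Median depth in the class was 3418, 6192 and 9937 UMIs per cell. Ribosomal RNA and repeats took 9.08%, 5.47% and 3.45% of its UMIs. Markers of hepatocytes summed to 1444, 1789 and 1903 CPM in it, and markers of Kupffer cells to 237, 347 and 382 CPM. Cluster-leading genes were chosen after their values were seen.

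The comparison of IDD+HTF with IDD asks how liver cells differ when iron arrives bound to transferrin, and in particular whether Bmp6 differs in the endothelial cells. Bmp6 (ENSMUSG00000039004.6) encodes a secreted BMP ligand that drives hepcidin in hepatocytes and lies on chromosome 13 at 38345107 to 38500302 of GRCm38. In sinusoidal endothelial-like cells (clusters 1, 2, 14 and 18) it stood at 102 CPM in IDD+HTF and 67.9 CPM in IDD, 1.5-fold higher (1.21 to 1.90). Bmp2, the other BMP ligand these cells make (chromosome 2, 133552159 to 133562885), was 1.47-fold higher (1.40 to 1.53). The ferritin subunits that store iron were higher too, Ftl1 by 1.54-fold (1.44 to 1.64) and Fth1 by 1.53-fold (1.40 to 1.67), as was the iron exporter ferroportin, Slc40a1, by 1.62-fold (1.40 to 1.89). Hmox1, which breaks down heme, was 1.77-fold higher (1.28 to 2.5), and RNA of Kupffer cells, read from their markers, would bring 21.6 of its 54.7 CPM in IDD+HTF and 16.9 of its 31.0 CPM in IDD. Hmox1 and Fth1 lay under their levels in droplets with 100 or fewer UMIs in both libraries, Hmox1 with 105 and 43.5 CPM there in IDD+HTF and IDD and Fth1 at 667 and 437 CPM against 1370 and 823. Ftl1 did so in IDD+HTF, at 1263 against 1293 CPM. Hepatocyte markers, Alb among them, summed to 1789 and 1444 CPM in the class in IDD+HTF and IDD, against 7965 and 4675 CPM of Alb alone in those droplets. Free RNA of that makeup can thus be only a part of these levels, and the folds are open in size.

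Among the 12 fixed genes, Id1, a target of BMP signalling (chromosome 2, 152736251 to 152737410), was 1.59-fold higher (1.41 to 1.79), although within cluster 2 alone its log2 ratio was −0.01. The inhibitory Smads, also BMP targets, were not higher, with a log2 ratio of −0.24 for Smad7 and of −0.14 for Smad6, which TMM scaling brings to 0.00. The transferrin receptor Tfrc (14 UMIs in IDD), the iron importer Slc39a14 (9 UMIs) and the NRF2 target Nqo1 (8 UMIs) were too sparse in IDD for a direction. Nqo1 lay at the 0th percentile among 246 genes of like expression. Those genes needed at least 50 UMIs in the pair of libraries, which Nqo1 did not reach, so nothing is read from that place. Bmp6 lay at the 94.7th percentile among 1687 genes of like expression, Hmox1 at the 98.2nd among 2340, Ftl1 at the 87.1st among 69 and Bmp2 at the 71.4th among only 20. Of 22 measured iron handling genes, 6 were at least 1.5-fold higher and 1 was lower, with Hfe, a regulator of hepcidin, at log2 0.78. Of 11 measured BMP ligands and targets, 2 were higher and 0 lower.

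Immediate early and dissociation genes, which respond within minutes to handling as well as to signals, formed the largest group, with 17 of 22 higher and 0 lower and a median log2 of 0.78. Examples were the heat shock genes Dnajb1 at log2 1.34 and Hspa1a at 1.15, and Fosb at 1.26 and Fos at 1.08. Within cluster 1 alone 8 of the list were higher, and within cluster 2 alone 6. NF-kB and cytokine genes followed, with 8 of 14 higher and 0 lower, among them the neutrophil chemokine Cxcl1 at log2 2.02, the adhesion molecule Icam1 at 1.09, Cxcl10 at 0.91 and Il1a at 0.90. Within cluster 1 alone 3 of these were higher. In the interferon response 6 of 20 were higher and 0 lower, led by the ubiquitin-like Isg15 at 2.14. In the acute phase list 6 of 10 were higher and 0 lower, with Mt1, a metallothionein that binds zinc, at 0.84 and the fibrinogen chains Fgg at 1.01 and Fgb at 0.96. The sums of hepatocyte markers given above were higher in IDD+HTF as well.

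Sterol synthesis genes were lower, 5 of 13 against 1 higher, with Hmgcs1 at log2 −1.28 and Idi1 at −1.67, both enzymes of the mevalonate pathway. Its median of −0.45 lay at the 0.41st percentile of random lists. NRF2 targets, genes of the antioxidant response, showed little difference, with 2 of 21 higher, 1 lower and a median log2 of 0.07. In the angiocrine list 4 of 12 were higher and 2 lower, with Ccn2 at log2 1.45, Inhbb at 0.86 and Angpt2 at 0.95. In the cell cycle list 4 of 12 were higher and 2 lower, with Cenpf at 1.24 and the cell cycle inhibitor Cdkn1a at 1.00. Other lists had few members past 1.5-fold. Higher and lower counts were 1 and 1 of 10 BMP receptors, 1 and 0 of 9 lipid peroxidation genes, 2 and 0 of 14 stress and unfolded protein response genes, and 3 and 1 of 16 hypoxia genes. They were 1 and 0 of 10 heme recycling genes, 1 and 0 of 13 heme synthesis genes, 1 and 2 of 10 pericentral genes and 1 and 0 of 10 periportal genes. They were 2 and 2 of 17 endocytic receptors, 2 and 2 of 12 clock genes, and 1 and 1 of 11 fasting genes. The sex check had 0 and 0 of 4, with Y-linked genes present in every library.

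The genes that stood furthest apart in these cells included Fzd6, a Wnt receptor, 11.1-fold higher (4.25 to 41.1), and Cd59a, which protects cells from complement, 4.48-fold higher (3.75 to 5.38). Isg15 was 4.40-fold higher (3.45 to 5.68), Cxcl1 4.04-fold (2.72 to 6.26), Sec61g, a part of the protein translocon, 3.70-fold (2.60 to 5.44), and Lyve1, a hyaluronan receptor of these cells, 2.81-fold (2.53 to 3.14). Gm25541 had 96 UMIs in IDD+HTF against 1 in IDD, a ratio of 23.4 (4.09 to 932). Gm10076, at log2 3.77, and Gm5148, at 2.04, share reads with close copies and are uncertain. Among genes lower in IDD+HTF were AA474408, 4.22-fold (3.70 to 4.82), the homeobox gene Six4, 5.21-fold (3.14 to 8.70), and the growth factor Pdgfb, 3.74-fold (2.37 to 5.87). Gm26686, Rbfa, Zfp872, Gm38243, Olfr898 and Trim5 were lower by log2 ratios between −2.29 and −1.67. Of 10601 measured genes, 270 were at least 2-fold higher and 299 lower, and TMM scaling made this 406 and 197 with the median log2 moving from 0.01 to 0.16. Median-of-ratios scaling gave 448 and 176.

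The comparison of IDD+HID with IDD asks how liver cells differ after 18 h of dietary iron, the arm that the series title's question about iron outside transferrin bears on. Bmp6 in sinusoidal endothelial-like cells (clusters 1, 2, 14 and 18) stood at 157 CPM in IDD+HID, 2.31-fold higher than in IDD (1.88 to 2.88), at the 98.7th percentile among 1309 genes of like expression. Hmox1 (chromosome 8, 75093621 to 75100589) was 5.37-fold higher (3.96 to 7.47), with 18.0 of its 166 CPM that RNA of Kupffer cells would bring, and Nqo1, an antioxidant enzyme (chromosome 8, 107388225 to 107403206), 4.92-fold (2.47 to 11.5). Ftl1 (chromosome 7, 45457944 to 45459884) was 3.5-fold higher (3.30 to 3.72), Slc40a1 (chromosome 1, 45908068 to 45926523) 2.71-fold (2.36 to 3.13), and Fth1 (chromosome 19, 9980598 to 9985098) 2.02-fold (1.86 to 2.20). Fth1, at 881 CPM in IDD+HID and 437 in IDD, lay under its 1641 and 823 CPM in droplets with 100 or fewer UMIs. Hepatocyte markers, Alb among them, summed to 1903 and 1444 CPM in the class, against 11366 and 4675 CPM of Alb alone in those droplets. Free RNA of that makeup can thus be only a part of Fth1 here, and its fold is open in size. Bmp2 was 1.67-fold higher (1.6 to 1.74), at the 68.8th percentile among only 15 genes of like expression. It is among the leading genes of cluster 1, which held 24.6% of the class in IDD and 49.5% in IDD+HID, and was 1.41-fold higher within cluster 1 (1.32 to 1.51) and 1.75-fold within cluster 2 (1.66 to 1.86).

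**Figure D2:**
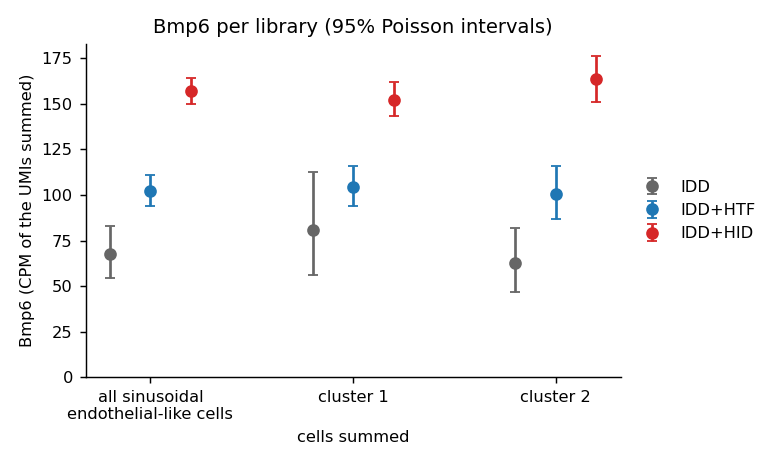
Bmp6 in sinusoidal endothelial-like cells per library, as CPM with exact Poisson 95% intervals that cover counting error only. The values were 67.9, 102 and 157 CPM from 92, 569 and 1871 UMIs.

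Bmp6 was detected in few cells at equal depth, and detection followed the same order. With each cell thinned to 1000 UMIs, 5.77% of the sinusoidal endothelial-like cells of IDD had a Bmp6 UMI (3.57 to 8.76), 8.64% of IDD+HTF (6.79 to 10.8) and 13.4% of IDD+HID (11.5 to 15.5). Unthinned shares, at the median depths of 3418, 6192 and 9937 UMIs, were 20.3%, 41.1% and 60.7%. As background, hepatocyte-like cells (clusters 5, 6 and 7), at median depths of 2116, 2151 and 2245 UMIs, gave 0 of 244 cells in IDD, which allows a share of up to 1.23%, and thinned shares of 0.0175% and 0.489% in the other libraries. B-like cells, at median depths of 4041, 3600.5 and 4546.5 UMIs, gave 0 of 91 cells (up to 3.30%), 0 of 180 (up to 1.67%) and 0.0858%. The order was not particular to the sinusoidal class. Stellate-like cells gave thinned shares of 0.429%, 3.27% and 4.44%, and vascular endothelial-like cells, 38 of them in IDD, gave 0.587%, 4.26% and 6.74%. Markers of sinusoidal endothelial cells were found in both of these classes. Sinusoidal endothelial-like cells held 92 of 104, 569 of 715 and 1871 of 2286 Bmp6 UMIs found in cells, or 88.5%, 79.6% and 81.8%. Within cluster 1 the Bmp6 log2 ratio of IDD+HID over IDD was 0.92 (fold 1.34 to 2.74), and within cluster 2 it was 1.39 (fold 1.98 to 3.53). Over IDD for IDD+HTF the same ratios were 0.37 (fold 0.908 to 1.90) and 0.69 (fold 1.18 to 2.23).

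NRF2 targets, which showed little difference in IDD+HTF over IDD, had 12 of 24 higher, 2 lower and a median log2 of 0.59, above all 10000 random lists. Besides Hmox1 and Nqo1, Gclm, a subunit of the enzyme that starts glutathione synthesis, stood at log2 1.73, and Blvrb, which reduces biliverdin, at 1.54. Heme recycling genes had 6 of 11 higher and 0 lower, with the heme-responsive repressor Bach1 at log2 0.62 and the heme transporter Slc48a1 at 0.81. Of 25 measured iron handling genes 9 were higher and 1 lower. They include Hamp at log2 1.67, but its UMIs in these cells (391 against 14) come with a thinned share of cells of 3.29%, which lies under the 3.76% of T-like cells, and are read as free RNA. Of 12 BMP ligands and targets 4 were higher and 0 lower, Id1 among those under 1.5-fold, at 1.29-fold (1.15 to 1.45) and log2 0.02 within cluster 2. Smad6 was 1.42-fold lower (1.25 to 1.61). Smad7, at log2 −0.15, had no firm direction because TMM scaling gives 0.09, and Tfrc (96 against 14 UMIs) and Slc39a14 (56 against 9) were too sparse.

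Immediate early genes were higher here as well, 16 of 22 against 0 lower, led by Fosb, a member of the AP-1 family, 7.81-fold (6.65 to 9.24), Fos at log2 1.75, Klf4 at 1.35 and Egr1 at 1.30. Within cluster 1 alone 7 were higher and within cluster 2 alone 12. NF-kB and cytokine genes had 10 of 16 higher and 1 lower, with Cxcl1 at log2 1.97, Socs3, an inhibitor of cytokine signalling, at 1.56, Cxcl10 at 1.42 and Nfkbiz at 0.95. Within cluster 1 alone 5 were higher. In the interferon response 6 of 20 were higher and 1 lower, with Isg15 5.30-fold higher (4.18 to 6.81) and Irf1 at log2 0.78. The acute phase list had 4 of 10 higher and 1 lower, with the metallothioneins Mt1 4.19-fold (3.88 to 4.53) and Mt2 3.96-fold (3.37 to 4.69) higher. Free RNA of hepatocytes was higher too, with Alb in droplets of 100 or fewer UMIs at 4675 CPM in IDD, 7965 in IDD+HTF and 11366 in IDD+HID.

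Sterol synthesis genes were lower, 6 of 13 against 0 higher, among them Idi1 at log2 −1.80, Hmgcs1 at −0.89 and the regulator Srebf2 at −0.99. Angiocrine factors had 2 of 14 higher and 5 lower, with the lymphangiogenic Vegfc at −1.48 and Inhbb, a subunit of activin B, at 1.10. Clock genes had 2 of 12 higher and 3 lower, Nr1d2 at 1.76 and Bhlhe41 at −1.21, in mice whose time of collection is not given. Cell cycle genes had 4 of 15 higher and 4 lower, Cdkn1a at 1.71 and Cenpf at −1.63. Of the endocytic receptors 5 of 17 were higher and 2 lower, with the lysosomal protease Ctsl at 0.87. Of the remaining lists, BMP receptors had 3 of 12 higher and 1 lower, lipid peroxidation genes 2 and 1 of 9, stress and unfolded protein response genes 2 and 0 of 14, and hypoxia genes 1 and 3 of 16. Heme synthesis genes had 1 and 0 of 14, pericentral genes 1 and 1 of 10, periportal genes 1 and 1 of 10 (Ednrb at 1.45 and the notch ligand Dll4 at −0.66), fasting genes 1 and 2 of 11 and the sex check 1 and 2 of 4.

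Other genes far apart in the sinusoidal endothelial-like cells were Cd59a, 4.38-fold higher (3.68 to 5.25), Fzd6, 8.81-fold (3.41 to 32.6), Gm26802, 7.18-fold (3.62 to 16.7), and Gm26532, 5.26-fold (3.6 to 8.02). Among those lower were Pdgfb, 14.1-fold (8.33 to 24.2), Six4, 13.9-fold (8.14 to 24.3), and Cyp26b1, which degrades retinoic acid, 4.22-fold (3.89 to 4.56). The small nuclear RNA Rn7sk was 7.00-fold lower (5.28 to 9.26), while ribosomal RNA and repeats were also a smaller part of the UMIs. AA474408, Gm26600, Gm15564, Gm49628 and Gm45684 were lower by log2 ratios between −3.14 and −2.31, and Hist1h2be, at −2.84, is uncertain because it shares reads with copies. Of 12218 measured genes 500 were at least 2-fold higher and 1148 lower. With TMM scaling these were 975 and 630, the median log2 moving from −0.02 to 0.23, and with median-of-ratios scaling 1125 and 562.

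**Figure D3:**
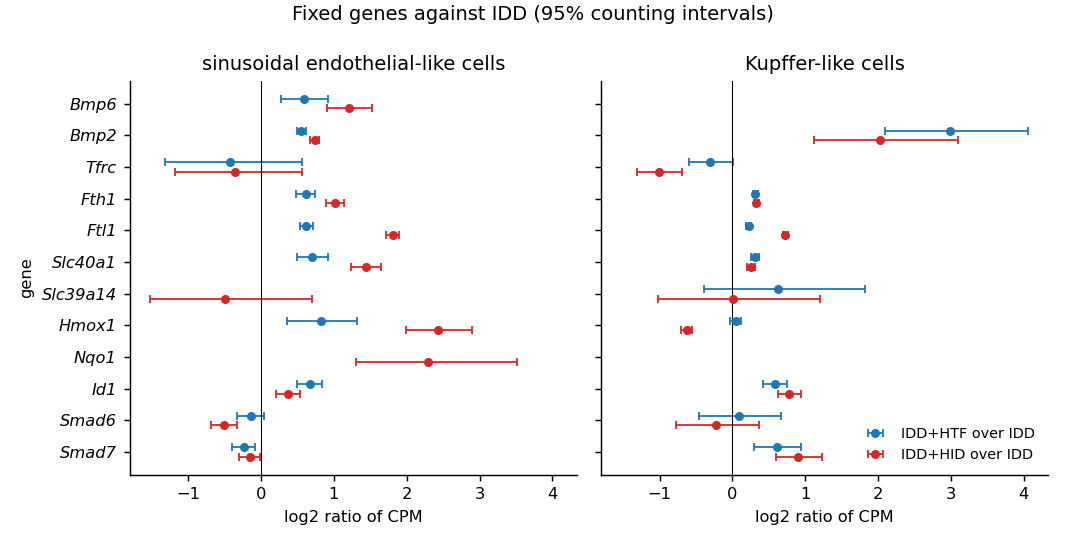
Log2 ratios over IDD of the 12 fixed genes in sinusoidal endothelial-like and in Kupffer-like cells, with exact 95% intervals. Genes with under 50 UMIs in the pair of libraries have no point, such as Nqo1 and Slc39a14 for IDD+HTF in the sinusoidal endothelial-like cells. In sinusoidal endothelial-like cells Hmox1 reached 2.42 in IDD+HID and 0.82 in IDD+HTF.

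**Figure D4:**
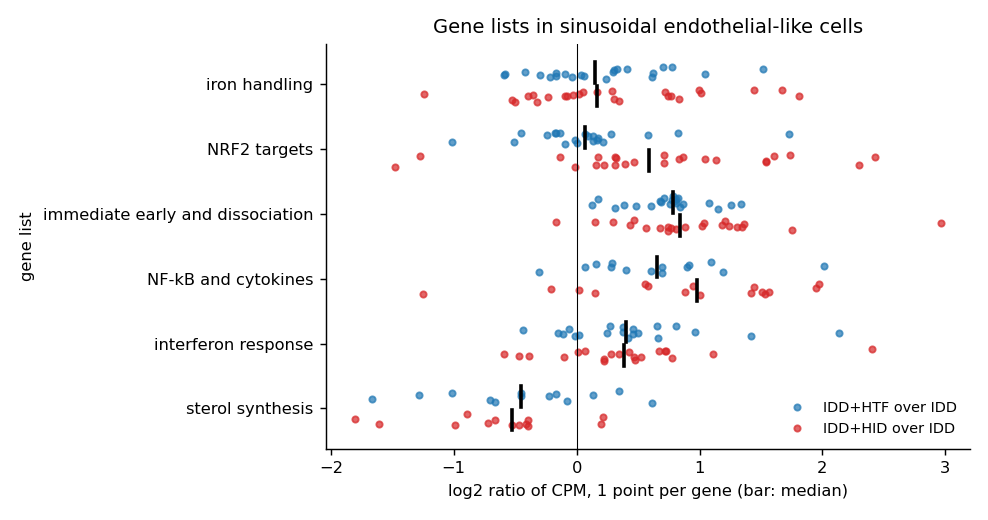
Log2 ratios over IDD of the measured genes of chosen lists in sinusoidal endothelial-like cells, with a point for each gene and a bar at each list median. The lists shown are iron handling, NRF2 targets, immediate early and dissociation, NF-kB and cytokines, interferon response and sterol synthesis. NRF2 targets had a median of 0.59 in IDD+HID and 0.07 in IDD+HTF.

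The comparison of IDD+HID with IDD+HTF sets the 2 ways of giving iron against each other. They differ in more than route, with an injection of 10 mg of holo-transferrin at a time not given against 18 h of a diet with 2% carbonyl iron. The route cannot be told apart from the amount of iron, its timing or the handling. In sinusoidal endothelial-like cells (clusters 1, 2, 14 and 18) Bmp6 was 1.54-fold higher after the high-iron diet (1.40 to 1.69), at the 98.3rd percentile among 1142 genes of like expression. Bmp2 was 1.14-fold higher (1.12 to 1.16). Nqo1 was 5.78-fold higher (3.93 to 8.82), Hmox1 3.04-fold (2.69 to 3.44), Ftl1 2.28-fold (2.22 to 2.33), Slc40a1 1.67-fold (1.57 to 1.77) and Fth1, under its level in small droplets, 1.32-fold (1.27 to 1.37). Of 24 NRF2 targets 13 were higher and 1 lower, with a median log2 of 0.84, and Gclm stood at log2 1.52 and Blvrb at 0.96. The BMP targets Id1 and Smad6 were 1.23-fold (1.17 to 1.30) and 1.29-fold (1.20 to 1.39) lower, and Smad7 was at log2 0.08.

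Fewer immediate early genes passed 1.5-fold between these libraries than over IDD, with 8 of 22 higher, among them Fosb at log2 1.71 and Fos at 0.67, and 2 lower. NF-kB genes had 5 of 17 higher and 1 lower, with Socs3 at 0.87. The acute phase list had 2 of 11 higher, Mt2 at 1.53 and Mt1 at 1.22, and 3 lower. Interferon genes had 1 of 20 higher and 0 lower. Iron handling genes had 3 of 26 higher and 1 lower. Periportal genes had 1 of 10 higher and 2 lower, with a median of −0.41, under nearly all random lists, Dll4 at −0.76 and Ednrb at 1.73. Of 13102 measured genes 147 were at least 2-fold higher and 521 lower, which TMM scaling made 210 and 388. The libraries differ in depth in every comparison, and each holds 1 mouse. The filling of this class differs in the comparisons with IDD, while it was nearly alike in IDD+HID and IDD+HTF. Cluster 1 made up 49.5% and 52.6% of the class in them and cluster 2 made up 36.7% and 36.5%.

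In Kupffer-like cells (clusters 3 and 9) the same comparisons ask how the macrophages that recycle iron from red cells differed. In IDD+HID the neutrophil chemokine Cxcl2 was 8.14-fold higher than in IDD (6.95 to 9.59), at 944 against 116 CPM. Hmox1, the enzyme of heme breakdown, was 1.55-fold lower (1.47 to 1.63), at 802 against 1240 CPM. Cluster 9, which has Hmox1 among its leading genes, held 46.7% of the class in IDD and 20.3% in IDD+HID, and the log2 ratio of Hmox1 was −0.59 within cluster 3 and −0.997 within cluster 9. The thinned share of cells with a Hmox1 UMI was alike, at 41.8% in IDD (34.6 to 49.3) and 41.2% in IDD+HID (37.3 to 45.2), at median depths of 4835.5 and 13202 UMIs. Tfrc was 2.01-fold lower (1.61 to 2.49), and Ftl1 was 1.66-fold higher (1.62 to 1.70). Slc40a1 was 1.19-fold higher (1.15 to 1.24) and Fth1 1.26-fold (1.23 to 1.29). The BMP targets Id1 and Smad7 were 1.71-fold (1.54 to 1.91) and 1.87-fold (1.52 to 2.34) higher, while Smad6, at log2 −0.22, had an interval that includes 0.

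Of their 22 NF-kB and cytokine genes 12 were higher in IDD+HID and 4 lower, with Tnfaip3, a brake on NF-kB, at log2 2.18, Ccl2 at 1.97 and Ccl3 at 1.65. Immediate early genes had 16 of 22 higher and 0 lower, with Fosb at 2.04 and Klf4 at 1.92. BMP ligands and targets had 6 of 10 higher and 1 lower, Hes1 at −1.34. The NRF2 targets did not stand apart, with 1 of 22 higher, 1 lower and a median log2 of 0.02, and Nqo1 had 0, 0 and 3 UMIs. Iron handling genes had 7 of 22 higher and 1 lower, and cell cycle genes 1 of 12 higher and 5 lower, with Mcm6 at −2.04. Acute phase genes had 7 of 9 higher and 1 lower, with Fgb at 2.15, while hepatocyte markers in the class summed to 583, 964 and 1185 CPM in IDD, IDD+HTF and IDD+HID. Markers of sinusoidal endothelial cells summed to 422, 699 and 569 CPM, and Bmp2, which had 10 UMIs in IDD, is read as RNA of those cells. Other genes far apart were Gm26532, 15.4-fold higher (9.13 to 28.2), and the transcription factor Egr2, 7.42-fold (4.72 to 12.4). Gm4759 had 247 against 2 UMIs, a ratio of 20.7 (5.66 to 172), and Gm34084 had 125 against 0, at least 6.97-fold higher. Efr3b, Gm36839, Vaultrc5, 4930589L23Rik and Art2b were lower, by log2 ratios from −4.48 to −2.21.

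In IDD+HTF over IDD the MHC class II chains H2-Eb1 and H2-Ab1 of the Kupffer-like cells were 4.15-fold (4.01 to 4.29) and 3.78-fold (3.67 to 3.90) lower, and Ciita, their master regulator, 4.47-fold lower (3.52 to 5.69). B cell markers in the class summed to 82.8 CPM in IDD and 45.1 CPM in IDD+HTF, and cluster 9 held 46.7% and 28.3% of its cells. Cd55, which restrains complement, was 7.93-fold higher (6.02 to 10.7). Hmox1 was alike, at 1.03-fold (0.978 to 1.09), as was Tfrc, 1.23-fold lower with an interval from 0.996 to 1.52. Ftl1 was 1.17-fold (1.14 to 1.20), Fth1 1.24-fold (1.21 to 1.28) and Slc40a1 1.24-fold (1.19 to 1.29) higher. Iron handling genes had 7 of 20 higher and 0 lower, Ncoa4, which sends ferritin to lysosomes, at log2 0.62 and Hfe at 0.86. Stress and unfolded protein response genes had 5 of 14 higher and 0 lower, with Herpud1 at 1.71, and immediate early genes 9 of 22 higher and 0 lower. NF-kB genes had 8 of 21 higher and 1 lower, with Ccl3 at 1.26, Socs3 at 1.64 and Cxcl9 at −0.99. AC166102.1 (138 against 0 UMIs), Prss29 (135 against 0) and Nphs1 (78 against 0) were at least 10.0-fold, 9.78-fold and 5.65-fold higher, which is open to how reads were assigned in each library. Itgb7 was 6.01-fold lower (3.81 to 9.55), Efr3b at log2 −3.56 turned to 0.42 without clusters of shallow cells, and Gm10076 is uncertain. Of 9767 measured genes 452 were at least 2-fold higher and 111 lower in IDD+HTF, and of 10260 genes 504 and 238 in IDD+HID.

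In hepatocyte-like cells (clusters 5, 6 and 7) the question is hepcidin, the hormone encoded by Hamp that blocks iron export (ENSMUSG00000050440.8, chromosome 7, 30942368 to 30944032). In IDD+HID Hamp was 5.42-fold higher than in IDD (4.93 to 5.97), a log2 ratio of 2.44 that was 1.52 with TMM and 1.59 with median-of-ratios scaling, and its neighbour Hamp2 (30922372 to 30924681) was 10.0-fold higher (6.38 to 16.7). With TMM scaling the log2 IDD+HID over IDD of Hamp2 in hepatocyte-like cells went from 3.33 to 2.41. The libraries filled the clusters unequally, with 115, 485 and 33 cells in cluster 5, 71, 306 and 52 in cluster 7 and 58, 198 and 174 in cluster 6, which has Hamp among its leading genes. Within cluster 6 Hamp was 1.97-fold higher in IDD+HID (1.78 to 2.18). With cells thinned to 1000 UMIs, 11.4% of hepatocyte-like cells of IDD had a Hamp UMI (7.67 to 16), 21.9% of IDD+HTF (19.3 to 24.6) and 77.8% of IDD+HID (72.2 to 82.7), at median depths of 2116, 2151 and 2245 UMIs. Unthinned shares were 17.6%, 36% and 88.0%. As background, 1.16%, 1.21% and 3.29% of sinusoidal endothelial-like cells (median depths 3418, 6192 and 9937 UMIs) had a thinned Hamp UMI, and unthinned 3.44%, 6.11% and 20.7%.

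**Figure D5:**
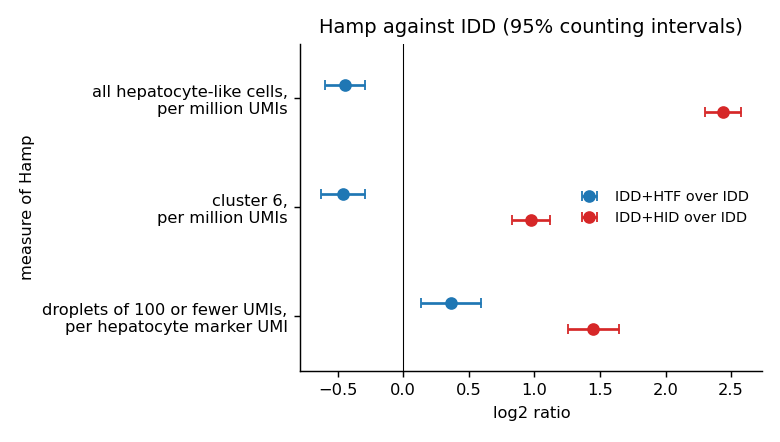
Log2 ratios of Hamp over IDD, with 95% intervals that cover counting error only. They are given for hepatocyte-like cells over the whole class and within cluster 6. Hamp per hepatocyte marker UMI in the small droplets that free RNA was read from is given as well. Within cluster 6 the log2 ratios were −0.46 in IDD+HTF and 0.98 in IDD+HID. The CPM behind them were 2376, 1729 and 4671 in IDD, IDD+HTF and IDD+HID.

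Between IDD+HTF and IDD no order of Hamp can be read. Its log2 ratio was −0.45 by CPM, but its thinned share of cells was the higher one in IDD+HTF and 3 of 17 alternative settings turned its sign. The clearest difference there lay in sterol synthesis, with 0 of 15 genes higher and 12 lower and a median log2 of −1.21, under all 10000 random lists. Sqle, which makes squalene epoxide, was 13.8-fold lower (7.61 to 26.3), and Fdps and Pmvk of the mevalonate pathway were 7.25-fold (5.21 to 10.2) and 5.71-fold (3.86 to 8.53) lower. Fasn, the fatty acid synthase, was 9.08-fold lower (7.36 to 11.3) and Acly, which supplies its acetyl-CoA, 5.79-fold (4.91 to 6.83). NRF2 targets had 0 of 18 higher and 7 lower, with Me1 and Pgd, which make NADPH, both at log2 −2.18. Acute phase genes had 4 of 13 higher and 1 lower, Mt1 at −1.95, and stress and unfolded protein response genes 2 of 13 higher and 0 lower, with Xbp1 at 0.90. Alas1, the rate-limiting enzyme of heme synthesis, was 11.9-fold higher (4.58 to 44.2), and Onecut1, a hepatocyte transcription factor, at least 14.4-fold (175 against 0 UMIs). Slc25a30 (2 UMIs in IDD), Arid5b (3) and B3galt1 (3) were higher by ratios of 18.7 (5.08 to 156), 14.3 (4.80 to 69.8) and 12.7 (4.26 to 62.2).

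In IDD+HID over IDD sterol synthesis genes of the hepatocyte-like cells had 0 of 14 higher and 9 lower, with Sqle at −3.44, and fasting and fat oxidation genes 11 of 13 higher and 2 lower, with Pck1, of gluconeogenesis, at log2 2.43. Fasn was 36.3-fold lower (20.4 to 71.0), Thrsp, which promotes lipogenesis, 24.6-fold (18.2 to 34.0), Elovl6, a fatty acid elongase, 19.5-fold (11.1 to 37.4), and Acly 14.4-fold (10.3 to 20.8). Mup18, a major urinary protein, was 27.2-fold lower (10.2 to 103). Cyp4a10 (142 against 0 UMIs) and Cyp4a14 (103 against 0), fatty acid hydroxylases under PPAR alpha, were at least 31.8-fold and 23.0-fold higher. Acot1 (93 against 0) was at least 20.8-fold higher, Eci2, of fat oxidation, 17.1-fold (9.65 to 33.5), and Alas1 24.7-fold (9.43 to 91.7). TMM scaling lowers the log2 ratios of this comparison by the same amount, so that lower folds grow and higher folds shrink. Excepted are genes with 0 UMIs in a library whose direction becomes open, such as Bmp6 (6 against 0 UMIs), set from 0.42 to 0. TMM scaling takes the log2 IDD+HID over IDD of Fasn in hepatocyte-like cells from −5.18 to −6.10 and the log2 IDD+HID over IDD of Alas1 in hepatocyte-like cells from 4.62 to 3.70. Heme synthesis genes had 9 of 9 higher, with Cpox at 1.86, and NRF2 targets 13 of 18 higher and 3 lower, with Gstm1 at 2.96, Gclm at 2.11 and Pgd at −3.04. BMP ligands and targets had 6 of 6 higher, Id3 at 3.35 and Id1 (51 against 0 UMIs) at least 11.4-fold. Endothelial markers in these cells came to 72.5, 268 and 1305 CPM in IDD, IDD+HTF and IDD+HID. Id1 at 51.7 CPM and Bmp2 (107 against 0 UMIs) at 108 CPM lie under their 102 and 245 CPM in droplets with 100 or fewer UMIs, and neither is read as expressed by hepatocytes. Acute phase genes had 1 of 12 higher and 5 lower, with Saa1 at −1.55.

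These counts in hepatocyte-like cells lean on scaling. The median gene stood at log2 0.97 in IDD+HID over IDD. Ribosomal RNA and repeats took 28.5%, 31.3% and 7.08% of UMIs in IDD, IDD+HTF and IDD+HID. Leaving them out of the total took Hamp in IDD+HID over IDD only from log2 2.44 to 2.06, so they are at most a part of that shift. Of 2810 measured genes 1370 were at least 2-fold higher and 192 lower, against 322 and 564 with TMM scaling, which brought the median to 0.05, and 371 and 522 with median-of-ratios scaling. Relative to the all-gene median, list medians were 0.47 for NRF2 targets, 1.23 for fasting genes, 0.43 for heme synthesis, 2.03 for BMP ligands and targets, −0.45 for iron handling, −1.49 for the acute phase and −2.74 for sterol synthesis. The BMP list includes Hamp itself, and also Id1 and Bmp2, which are not read as expressed by hepatocytes. Its median is therefore not read as a response of hepatocytes alone. Ftl1 was 2.59-fold higher (2.46 to 2.73), a log2 ratio of 1.37 that TMM scaling makes 0.45, while Fth1, at log2 0.90, turned to −0.03 with TMM scaling. Tfrc was 6.71-fold lower (2.21 to 27.2), but at log2 −0.05 within cluster 6. Slc40a1 was 3.32-fold higher (1.95 to 5.96), with TMM scaling at log2 0.81, and its 85.2 CPM lie under the 266 CPM of droplets with 100 or fewer UMIs. Slc39a14, at log2 −0.70, was 1.28 within cluster 6. In IDD+HTF over IDD 255 of 3479 measured genes were at least 2-fold higher and 147 lower, with Ftl1 1.31-fold lower (1.24 to 1.38), at log2 0.06 within cluster 6, and Slc40a1 1.95-fold higher (1.17 to 3.44), at 50.1 CPM under the 234 CPM of such droplets. Hamp was 7.39-fold higher in IDD+HID than in IDD+HTF (6.95 to 7.85), a log2 ratio of 2.89 that was 1.87 with TMM scaling and 1.43 within cluster 6, and 2106 of 4280 genes were at least 2-fold higher and 405 lower between them, against 338 and 1077 with TMM scaling.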

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

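The tests in this part were set only after the results they bear on were seen, although the subtraction of free RNA and the list medians that they use were chosen before.

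Hmox1 and the NRF2 targets were higher in the sinusoidal endothelial-like cells of IDD+HID, and Hmox1 differed in direction between cell classes. Its log2 ratio of IDD+HID over IDD was 2.42 in sinusoidal endothelial-like cells and −0.63 in Kupffer-like cells (−0.59 and −0.997 within their clusters 3 and 9), while the 3.75 of hepatocyte-like cells rests on 20 UMIs at 20.3 CPM, under the 82.4 CPM of droplets with 100 or fewer UMIs, and the difference between classes was not tested. RNA of Kupffer cells in the endothelial class would bring 18.0 CPM of Hmox1 against the 166 CPM seen in IDD+HID, so it cannot account for that level, but it would bring 16.9 of 31.0 CPM in IDD and 21.6 of 54.7 CPM in IDD+HTF, so the folds over IDD are open in size. Free RNA cannot account for the group, since 13 NRF2 targets were at least 1.5-fold higher once it was subtracted, against 12 before. Dissociation genes were also higher in IDD+HTF over IDD, yet the NRF2 median there was only 0.0667. More dissociation genes were higher than lower in IDD+HID over IDD+HTF, Fosb among them, so stress of the tissue dissociation is not excluded. A response of these cells to dietary iron is the biological explanation the design offers and is consistent with these values, but with 1 mouse per group any other difference between the mice could give the same.

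Bmp6 was higher in the sinusoidal endothelial-like cells of IDD+HID than of IDD. Shallow depth or poorer RNA of the IDD library that acts on all genes of like expression would move them together, yet Bmp6 lay at the 98.7th percentile of such genes. That place cannot decide on losses of RNA that differ from gene to gene. Ribosomal RNA and repeats took 9.08% of the UMIs of the class in IDD and 3.45% in IDD+HID. Unequal filling of the clusters would remove the difference within clusters, yet the smaller of the log2 ratios within clusters 1 and 2 was 0.92, with an interval above 0. The dietary iron may account for the difference, but losses of RNA gene by gene and a difference between individual mice were not tested.

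Hamp was higher in the hepatocyte-like cells of IDD+HID. By counting error, unequal filling of the clusters was not the whole difference, because the lower interval end of the log2 ratio within cluster 6 was 0.83. That interval leaves out the spread between the 58 cells of IDD and the 174 of IDD+HID in cluster 6, so makeup within the cluster stays open. Unequal filling is likely a part of the difference, because the ratio within cluster 6 was 0.98 against 2.44 over the class. Calling of the cells and their class totals cannot give the whole difference, because the droplets with 100 or fewer UMIs, which use neither, gave 1.45 relative to hepatocyte markers, but scaling moves its size, to 1.52 with TMM and 1.59 with median-of-ratios factors. These droplets were set apart as data outside the cells, and Hamp per hepatocyte marker UMI in them was higher than in the control by log2 0.36 in IDD+HTF (0.14 to 0.59) and 1.45 in IDD+HID (1.25 to 1.64). The design offers the high-iron diet as the biological explanation. In these cells most fasting and fat oxidation genes were also higher than in the control, and Fasn was lower, as given above. With 1 mouse per group, iron cannot be told apart from feeding or any other difference between the mice.

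Cluster 20, left unnamed and used in no comparison, drew attention because it held 0 of 1311 cells of the control, which allows a share of up to 0.229%, against 0.500% of cells in IDD+HTF (16 cells) and 1.10% in IDD+HID (39 cells), with the Kupffer markers Vsig4 and Clec4f among its leading genes and a median of 25418 UMIs.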

How the results depend on the processing

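No paired analysis was possible because the labels give replicate 1 in each group, which is 1 library of 1 mouse each. The settings with clusters 1, 2 or 6 alone, with clusters 3 or 9 alone for Hmox1 in Kupffer-like cells, without clusters of shallow cells, without ribosomal RNA and repeats, without the 6% highest doublet scores and with a single thinning draw were added after the data were seen. Over 20 alternatives the log2 ratio of Bmp6 in sinusoidal endothelial-like cells ranged from 0.27 to 0.76 for IDD+HTF over IDD, from 0.92 to 1.5 for IDD+HID over IDD and from 0.54 to 1.13 for IDD+HID over IDD+HTF, and kept its sign in all. NRF2 targets higher in IDD+HID over IDD ranged from 8 to 17 over 24 alternatives. Hamp in hepatocyte-like cells kept its sign for IDD+HID over IDD (0.98 to 3.66) and IDD+HID over IDD+HTF (1.43 to 3.07) in all 17 alternatives, while for IDD+HTF over IDD it ranged from −1.08 to 0.64. Among the other gene values 2735 of 3280 stayed within their interval, 524 moved further and 21 reversed. A reversal was counted only for values at least 1.5-fold higher or lower whose log2 interval excludes 0. Sign changes of smaller values are counted among the rest. Ftl1 in hepatocyte-like cells, IDD+HTF over IDD, went from −0.39 to 0.06 in cluster 6 alone and is counted as moved. Of the other list counts 5903 of 7740 stayed within 1.5 times. Depth limits genes with few UMIs in IDD, such as Tfrc, Slc39a14 and Nqo1. The free RNA subtraction gives no value for hepatocyte-like cells, because it sets their markers to 0. Except where the construction of a setting (fewer UMIs, another minimum or fold) is the cause, the cause was not tested.

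Sinusoidal endothelial-like cells, 26.6%, 25.0% and 34.0% of IDD, IDD+HTF and IDD+HID, came to 22.0%, 21.4% and 28.6% with at least 500 UMIs. They came to 17.0%, 18.6% and 24.4% with no mitochondrial limit, to 16.9%, 18.4% and 24.6% by each cell's own marker sum, and to 23.7%, 22.5% and 31.7% at resolution 2. In IDD and IDD+HTF they came to 29.7% and 30.05% with at least 2000 UMIs, and in IDD+HTF to 31.1% with a UMI minimum per library and 27.9% with at most 10% mitochondrial UMIs. The share of them with a Bmp6 UMI was 20.3%, 41.1% and 60.7% without thinning and 11.6%, 16.5% and 24.5% after thinning to 2000 UMIs, by construction. A sum over cells thinned to 1000 UMIs gave 1.13 for Bmp6 in IDD+HID over IDD+HTF against 0.62. Id1 in IDD+HTF over IDD went from 0.67 to −0.0116 in cluster 2 alone.

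Hamp in IDD+HTF over IDD was −0.45, and −0.72 with at least 2000 UMIs, −1.08 with at most 10% mitochondrial UMIs, 0.55 with no such limit, −0.81 by own marker sum, 0.38 as the mean of per-cell CPM and 0.64 with cells thinned. In IDD+HID over IDD it was 2.44, and in the same order 2.20, 1.85, 3.05, 1.91, 3.45 and 3.66, then 1.52 with TMM, 1.59 with median-of-ratios factors, 2.06 without ribosomal RNA and repeats and 0.98 in cluster 6 alone. In IDD+HID over IDD+HTF it was 2.89 (2.885), and 2.5 with no mitochondrial limit, 2.72 by own marker sum, 1.87 with TMM, 1.96 with median-of-ratios factors, 3.07 as the mean of per-cell CPM, 3.02 with cells thinned, 3.01 without mitochondrial, ribosomal protein, hepatocyte and erythroid genes, 2.45 without ribosomal RNA and repeats and 1.43 in cluster 6 alone.

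In hepatocyte-like cells Fth1 in IDD+HID over IDD went from 0.90 to −0.0256 with TMM and −0.51 in cluster 6 alone, and over IDD+HTF from 0.76 to −0.26 with TMM, −0.17 with median-of-ratios factors and −1.12 in cluster 6 alone. Slc40a1 in IDD+HID over IDD+HTF went from 0.77 to −0.24 with TMM, −0.16 with median-of-ratios factors, −0.0495 as the mean of per-cell CPM and −0.42 with cells thinned. Slc39a14 in cluster 6 alone went from −0.70 to 1.28 over IDD and from −1.23 to 1.80 over IDD+HTF. Bmp2 in IDD+HTF over IDD went from 1.53 to −0.18 with doublets kept. In Kupffer-like cells Efr3b in IDD+HTF over IDD went from −3.56 to 0.42 without clusters of shallow cells. Bmp2 in IDD+HID over IDD went from 2.02 to −0.17 with at least 2000 UMIs, and over IDD+HTF from −0.96 to 0.60 with no mitochondrial limit, 0.42 by own marker sum, 0.56 at resolution 0.5, 0.18 at resolution 2 and 0.56 with cells thinned, where Slc39a14 went from −0.62 to 0.63.

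NRF2 targets higher in IDD+HTF over IDD were 2, and 4 with no mitochondrial limit and 1 in cluster 2 alone, with at least 200 UMIs per gene or under a 2-fold rule. In IDD+HID over IDD+HTF they were 13, and 7 under a 2-fold rule. All genes at least 2-fold higher and lower in sinusoidal endothelial-like cells in IDD+HTF over IDD were 270 and 299. They were 406 and 197 with TMM, 448 and 176 with median-of-ratios factors, 889 and 847 with cells thinned, 175 and 125 in cluster 2 alone, 555 and 945 with at least 20 UMIs per gene, 74 and 21 with at least 200, 900 and 4572 with no minimum, 1003 and 1103 under a 1.5-fold rule and 24 and 5 under a 4-fold rule, and 500 were higher in cluster 1 alone. In IDD+HID over IDD they were 500 and 1148, and in the same order 975 and 630, 1125 and 562, and 1208 and 1764. In cluster 1 alone they were 801 and 713, with at least 200 UMIs per gene 251 and 226, with no minimum 766 and 6876, at 1.5-fold 1632 and 2465 and at 4-fold 57 and 67. Lower genes were 509 in cluster 2 alone and 2371 with at least 20 UMIs. In IDD+HID over IDD+HTF they were 147 and 521, and 674 and 1413 with cells thinned, 366 and 1096 with at least 20 UMIs per gene, 58 and 138 with at least 200, 964 and 4236 with no minimum, 621 and 1526 at 1.5-fold and 9 and 44 at 4-fold, and 200 were lower in cluster 2 alone.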

Other observations

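In T-like cells all 13 measured cell cycle genes were at least 1.5-fold lower in IDD+HTF than in IDD, with a median log2 of −2.20, and 15 of 17 were lower and 1 higher in IDD+HID, with a median of −1.29. Between IDD+HID and IDD+HTF 10 of 15 were higher and 1 lower. The class held 82, 135 and 262 cells in IDD, IDD+HTF and IDD+HID, of which cluster 10 made up 63.4%, 54.1% and 57.3%. The number of cycling cells among them was not counted, and genes of this list that share such cells are not separate observations. In B-like cells the immediate early and dissociation genes, higher in endothelial and Kupffer-like cells, were lower, with 13 of 21 lower and 1 higher in IDD+HID over IDD (median log2 −0.80) and 6 lower and 2 higher in IDD+HTF over IDD (median −0.37). The heat shock gene Hspa1a stood at log2 −4.77 and Jun at −2.61 in IDD+HID over IDD.

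Vascular endothelial-like cells, compared only between IDD+HID and IDD+HTF because IDD held 38 of them, had 8 of 17 NRF2 targets higher and 0 lower, with a median log2 of 0.52, while markers of sinusoidal endothelial cells in them summed to 15038 CPM in IDD+HTF and 19553 CPM in IDD+HID. Hmox1 there was at 1.31, Slc40a1 at 1.5 and Ftl1 at 1.26. Stellate-like cells, which store retinoid and lay down matrix, had 13 of 20 NRF2 targets higher and 2 lower in IDD+HID over IDD, and 20 of 22 immediate early genes higher and 0 lower. In the same cells markers of sinusoidal endothelial cells summed to 4067 CPM in IDD, 12605 in IDD+HTF and 16170 in IDD+HID.

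Gm10076 was at log2 3.77 in IDD+HTF over IDD in sinusoidal endothelial-like cells, 3.28 in Kupffer-like, 3.39 in B-like and 3.47 in T-like cells. Summed with Rpl41, with which it shares reads, the ratios were 0.47, 0.23, 0.30 and 0.11. Cluster 24, with 1, 7 and 0 cells in IDD, IDD+HTF and IDD+HID, was led by Ctrb1, Clps, Prss2 and Pnlip. Cluster 11, with 53, 68 and 153 cells, had markers of dendritic and monocyte types nearly alike, and cluster 12, with 64, 162 and 24 cells, had hepatocyte markers under the minimum for a name. These clusters and the genes of this part were chosen after their values were seen.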
